A study of Leucoraja erinaceus with 8 samples.

How the data were processed

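Raw transcript counts per probe target and segmented cell were deposited for 8 trunk sections, and per the labels they came from the Xenium In Situ platform with a custom panel. Per the labels the embryos were fixed in paraformaldehyde, embedded and sectioned. The software of the instrument, the segmentation setting and the quality filter on transcripts are not given in the sources used here. Each matrix held 300 genes, 20 negative control probes, 41 negative control codewords and 180 unassigned codewords. Only the gene counts entered the comparisons. LOC identifiers were matched to the RefSeq gene table of the little skate and are given as they stand. The labels name the embryo, the stage and the side of fin removal. Cell positions were not used here, so the side and the segment of a cell were not compared.

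The embryo was the replicate. Both sections of an embryo were summed for the stage tests, 2 embryos against 2, and each embryo lay on both slides. The sections on the 2 slides are paired because they come from the same animal. No section repeated another, with a chi-square per degree of freedom of 1762.6 or more over the 28 pairs of sections. Sections were the unit only in the slide tests, where embryo was a block, in a random-block alternative and in a search for outlying sections, and cells were never the unit. The planned comparisons with their tests and thresholds, the gene lists and the rule for the genes named were set before the data were examined, and what was set or added later is named below.

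Cells with 20 or more gene counts were kept. For clustering, counts were scaled within each cell, log-transformed and reduced to 40 principal components, and clusters were found with leidenalg 0.10.2 on a graph of 15 neighbours at a resolution of 2.0. The 48 panel genes on the lists below were left out, so 252 genes formed the clusters. A sample of 15000 cells per section gave 30 clusters, and a classifier assigned all cells (84.0% agreement with the clustered cells). The 95976 cells of 5 neural clusters were clustered again from 60000 of them into 31 clusters, N0 to N30 (83.8% agreement). Clusters T0 and up are those of the first round. A different scaling in the first round was dropped after it gave poor agreement. No doublet caller was run, and a segment may hold RNA of more than 1 cell.

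Neural clusters were named by markers listed in advance, but the rule for calling a marker present was set after the clusters and their marker levels were seen and before any stage test. A marker counted as present at 5 times or more its share of counts in non-neural cells and at 10% or more of its level in the highest cluster. Other rules considered were a fixed level per 10000, 12 or 15% of the highest cluster, and folds over all cells. The sensory class needed all 3 of its markers on the panel, the motor class all 4 and the excitatory interneuron class at least 3 of 5. A cluster with a marker of glia or progenitors among its 10 leading genes was not named, which left out N15 (3 excitatory markers, gfap) and N17 (3 sensory markers, egr2b). N14 had 3 of 4 motor markers and N27 had 2 of 3 sensory markers. For the stage tests a class also lost clusters whose leading genes held more markers of other classes than of their own, which removed N0 (drgx) and N22 (runx2a), and these were tested by number after the data were seen. With no inhibitory or pan-neuronal marker on the panel, the interneuron class held excitatory interneuron-like clusters only, which is narrower than planned.

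Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM, filterByExpr, Benjamini-Hochberg at 0.05) in R 4.3.3, on sums per embryo for stage, on sections with embryo as a block for slide, and on sums per embryo and class with embryo as a block for classes. SE is the absolute log2 difference over the square root of F. Levels are counts per 10000 gene counts of the class, as mean ± SD over embryos or sections, without TMM. Class shares were tested with edgeR on cell numbers, and DESeq2 was not run on them. Gene lists were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry in limma 3.58.1, and adjusted over lists within a class. The lists held 1 HOX gene, 16 sensory subtype, 7 motor neuron subtype, 20 interneuron identity, 4 neuropeptide, 7 channel and receptor, and 4 guidance and adhesion genes on the panel. Lists overlap, so a gene can count in more than 1. For example, etv1, etv4, ret and runx1 are both sensory and motor neuron subtype genes. The HOX list was too short for a set test. For class comparisons only the 41 list genes that did not help to name clusters were reported.

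The genes named in a comparison were up to 10 per direction with the largest fold among those past the threshold, with at least 20 counts in the higher group and the same direction on both slides. Some genes that this rule picks are not reported here. Where under 5 genes passed, the 5 with the smallest p were named as not past the threshold. Neurotrophin receptor, ret, runx, isl1, mnx1, foxp1, aldh1a2, etv1, etv4, chat and HOX genes could be named whatever their test. tac1 in the sensory comparison and the levels of egr3 and gfap by cluster were added after the values were seen. Co-detection was measured in cells thinned to 100 counts, as log2 of the observed over the expected number of cells with both genes, with 0.5 cells added to each, per embryo, and tested by an exact sign-flip permutation over embryos.

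Alternatives were DESeq2 1.42.0, library totals without TMM, no filter on low-count genes, limma voom on 8 sections with embryo as a random block, each slide alone, a minimum of 10 (whole sections only) or 40 counts per cell, clusters from all panel genes, classes without N0 and N22, resolutions of 1.0 and 4.0, no replicate block, thinning to 50 counts or none, detection at 2 or more counts, and each embryo left out in turn. The correlation of sections of the same embryo was 0.762 in whole sections, 0.591 in N7, 0.489 in motor and 0.707 in interneuron-like cells, 0.637 in N0 and 0.568 in N22. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 was used for the rest.

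The stage tests of genes, the whole-section slide test and the 2 class contrasts were tested on simulated data with 60 changed genes, 20 each at 1.5, 2 and 4-fold, at the depth and spread of the real sums. Of 20 genes per fold the stage test recovered 1, 8 and 20 in whole sections (1 false call), 3, 9 and 20 in N7 (3 false), 5, 11 and 18 in motor neuron-like cells (3 false), 3, 9 and 17 in interneuron-like cells (0 false), 4, 5 and 18 in N0 (2 false) and 2, 15 and 17 in N22 (2 false). Most 2-fold stage differences in 4 of these 6 tests would therefore go unseen. The slide test recovered 18, 20 and 20 (5 false), the sensory test 3, 15 and 19 (0 false) and the motor test 14, 20 and 20 (3 false). A simulated raised list gave p of 3.03e-17 by camera at the preset correlation and 0.00219 by fry, and an unchanged list 0.552 and 0.499. The simulated genes varied independently, so this did not test how correlation between genes affects the set tests. Simulated pairs of genes gave co-detection values of 0.0 when independent, 1.74 in the same cells and -8.08 in separate cells.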

Results

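Transcripts of 300 genes were counted in place in trunk sections of little skate embryos. The little skate, Leucoraja erinaceus, is a cartilaginous fish. The Xenium platform images RNA bound by gene-specific probes and assigns each molecule to a segmented cell. The panel held 160 genes with a symbol and 140 with a LOC identifier alone. The 8 sections came from 4 embryos, and each embryo had 1 section on each of 2 slides. Embryos a and b were at stage 32, and embryos c and d were at stage 31+, just before it. Each section carried cord and ganglia from pectoral and pelvic levels. In every embryo 1 fin had been removed, on the right in embryo a and on the left in b, c and d. Cell positions were not used here, so neither the ablated side nor the segments were compared.

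The sections held 125982 to 193664 cells and 1290671 cells in all. Gene counts per section on slides 1 and 2 were 24317723 and 28042412 in embryo a, 25963861 and 26596070 in b, 19119354 and 21480859 in c, and 23401923 and 25199772 in d. The median cell held 78.0 to 129.0 gene counts. Cells with 20 or more gene counts were kept, 1126935 in total and 83.3 to 92.7% per section, and these held 98.9 to 99.6% of the gene counts. A negative control probe collected on average 0.0498 to 0.0855% of the counts of a gene.

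Cells taken as neural in the first round fell into 31 clusters, computed without the 48 genes of the lists. Of these genes 41 did not help to name clusters and were compared between classes. Not all 31 clusters need be neural. N30, with 50 cells, shared the leading genes vgll2a and LOC129715185 with T10, and N20 shared elf3 and lamp3 with T19. Clusters N7 and N22 carried the sensory neuron markers drgx, isl1a and ntrk2a, and their 5745 cells are called sensory neuron-like. Cluster N2, with 5109 cells, carried the motor neuron markers chata, isl1a, isl2a and mnx1. Clusters N0, N1, N5, N8, N11, N16 and N24, with 32382 cells, carried at least 3 of the excitatory interneuron markers barhl2, lhx5, lhx9, sim1a and tlx3b. The 10 leading genes of N0 held drgx and those of N22 held runx2a, markers of other cell types, and none of their own class, so N0 and N22 entered the comparisons between classes and the co-detection but not the stage tests of the classes. The panel had 0 markers of inhibitory interneurons, so these were not named. Among the leading genes of other clusters were olig2 in N6, N9 and N10, gfap in N9, N12 and N15, egr2b in N17, s100b in N18 and N28, gata3 in N13 and N23, and irx3a in N12 and N19.

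The first comparison asked which receptors, transcription factors, peptides and channels set ganglion neurons apart from cord neurons in this fish. runx3, which in mammals directs the proprioceptive lineage, stood at 63.7 ± 9.56 per 10000 gene counts in sensory neuron-like cells (SD, n = 4 embryos) and at 0.311 ± 0.0276 in motor and interneuron-like cells, a log2 difference of 8.21 (SE 0.18, adjusted p = 6.22e-07). Its relative runx1, tied in mammals to nociceptors, reached 13.1 ± 6.15 against 0.465 ± 0.0180, a log2 difference of 5.23. Of the channel genes, trpm2 was higher in sensory neuron-like cells by 8.32 (SE 0.39) on the log2 scale and kcnk18, which encodes a background potassium channel, by 7.84 (SE 0.50). calca, the precursor of the peptide CGRP, stood at 219 ± 45.8 against 31.9 ± 6.13, and ret, a receptor for ligands of the GDNF family, at 70.5 ± 10.9 against 28.3 ± 2.08. The ret difference came from N22, with 169 per 10000 against 12.8 in N7. With N0 and N22 left out of the classes it turned from 1.84 to -0.94 on the log2 scale (adjusted p = 0.0037), and that of etv4 went from 4.05 to 1.54. pou4f3, shox2 and calb2a were higher in sensory neuron-like cells by 5.65, 3.11 and 1.98 on the log2 scale.

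Cord neurons had far more of the glutamate receptor gene grm5b, at 52.0 ± 4.99 against 0.0607 ± 0.0235 in sensory neuron-like cells, a log2 difference of -9.25 (SE 0.22). The interneuron identity genes otpa, sp8b, prdm8b, bhlhe22, evx2, wt1b and calb1 followed, with log2 differences of -8.61, -7.69, -7.10, -5.75, -5.69, -5.42 and -4.39. The nitric oxide synthase gene nos1 was lower in sensory neuron-like cells as well, with a log2 difference of -5.70. hoxb4a, the 1 HOX gene on the panel, stood at 9.25 ± 1.82 against 41.1 ± 4.01. The motor neuron subtype genes foxp1b, etv1 and aldh1a2 had log2 differences of -1.64, -2.73 and -2.87. Of the genes named as lower here, etv1 and calb1 also stand on the sensory subtype list.

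By edgeR, 40 of the 41 list genes tested between these classes passed an adjusted p of 0.05, 14 higher in sensory neuron-like cells and 26 lower. The count adjusted over the list alone was 41. Of the sensory subtype list 14 of 15 genes passed, 11 of them higher. All 14 interneuron identity genes passed and 12 of them were lower, as were all 4 guidance genes. The 7 motor neuron subtype genes split into 3 higher and 4 lower, the 4 neuropeptide genes into 2 and 2, and 6 of 7 channel genes passed with 2 higher and 4 lower. The 3 higher motor neuron subtype genes, ret, etv4 and runx1, are also sensory subtype genes and count in both lists. The named genes differed in the same direction in 4 of 4 embryos. tac1, higher by the fit, had the higher level per 10000 in sensory neuron-like cells in 1 of 4 embryos, since the fit rescales each sum and the levels do not.

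The second comparison set motor neuron-like cells against excitatory interneuron-like cells. tac1, the precursor of substance P, reached 425 ± 94.6 per 10000 in motor neuron-like cells and 28.9 ± 2.82 in interneurons, a log2 difference of 3.97 (SE 0.12, adjusted p = 1.9e-08, n = 4 embryos). aldh1a2, whose enzyme makes retinoic acid in limb-innervating motor neurons of tetrapods, stood at 47.0 ± 19.9 against 4.26 ± 0.569, and foxp1b, which marks the same motor column there, at 88.8 ± 8.01 against 13.8 ± 1.49. Other cells held aldh1a2 as well. Over whole sections it stood at 32.6 ± 10.1 per 10000 on slide 1 and 27.6 ± 8.01 on slide 2 (SD, n = 4 sections each), and it led the unnamed cluster N26. RNA of neighbouring cells as a source of aldh1a2 in motor neuron-like cells was not tested. ret was 8.38-fold higher in motor neuron-like cells than in interneurons and calca 9.82-fold higher. sp8b, kcnk18, etv4, runx1 and onecut2 were higher by 2.69, 2.34, 2.34, 1.99 and 1.57 on the log2 scale, with kcnk18 and runx1 at or below 1.01 per 10000 in both classes. etv1 (-0.01) and runx3 (-0.05) did not pass.

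Interneuron-like cells led in the neuropeptide Y receptor gene npy1r, at 120 ± 7.93 against 13.3 ± 1.38 in motor neuron-like cells, and in hoxb4a, at 52.0 ± 4.86 against 10.8 ± 1.75. nos1, bcl11ba, bcl11aa, pou4f3, pou4f2, epha7 and shox2 followed with log2 differences of -2.45, -2.17, -1.94, -1.97, -1.84, -1.50 and -1.10. With N0 left out shox2 no longer passed (-0.44, adjusted p = 0.142). Of the 41 list genes 29 passed by edgeR, 16 higher and 13 lower in motor neuron-like cells, and 29 passed adjusted over the list alone. Among motor neuron subtype genes 6 of 7 passed, 5 of them higher. The counts were 12 of 14 for interneuron identity genes, 6 in each direction, and 9 of 15 for sensory subtype genes, 5 of them higher. ret, etv4 and runx1 are among the higher genes of both the motor neuron and the sensory subtype list. The other lists gave 4 of 4 neuropeptide genes, 3 of 7 channel genes and 2 of 4 guidance genes.

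**Figure D1:**
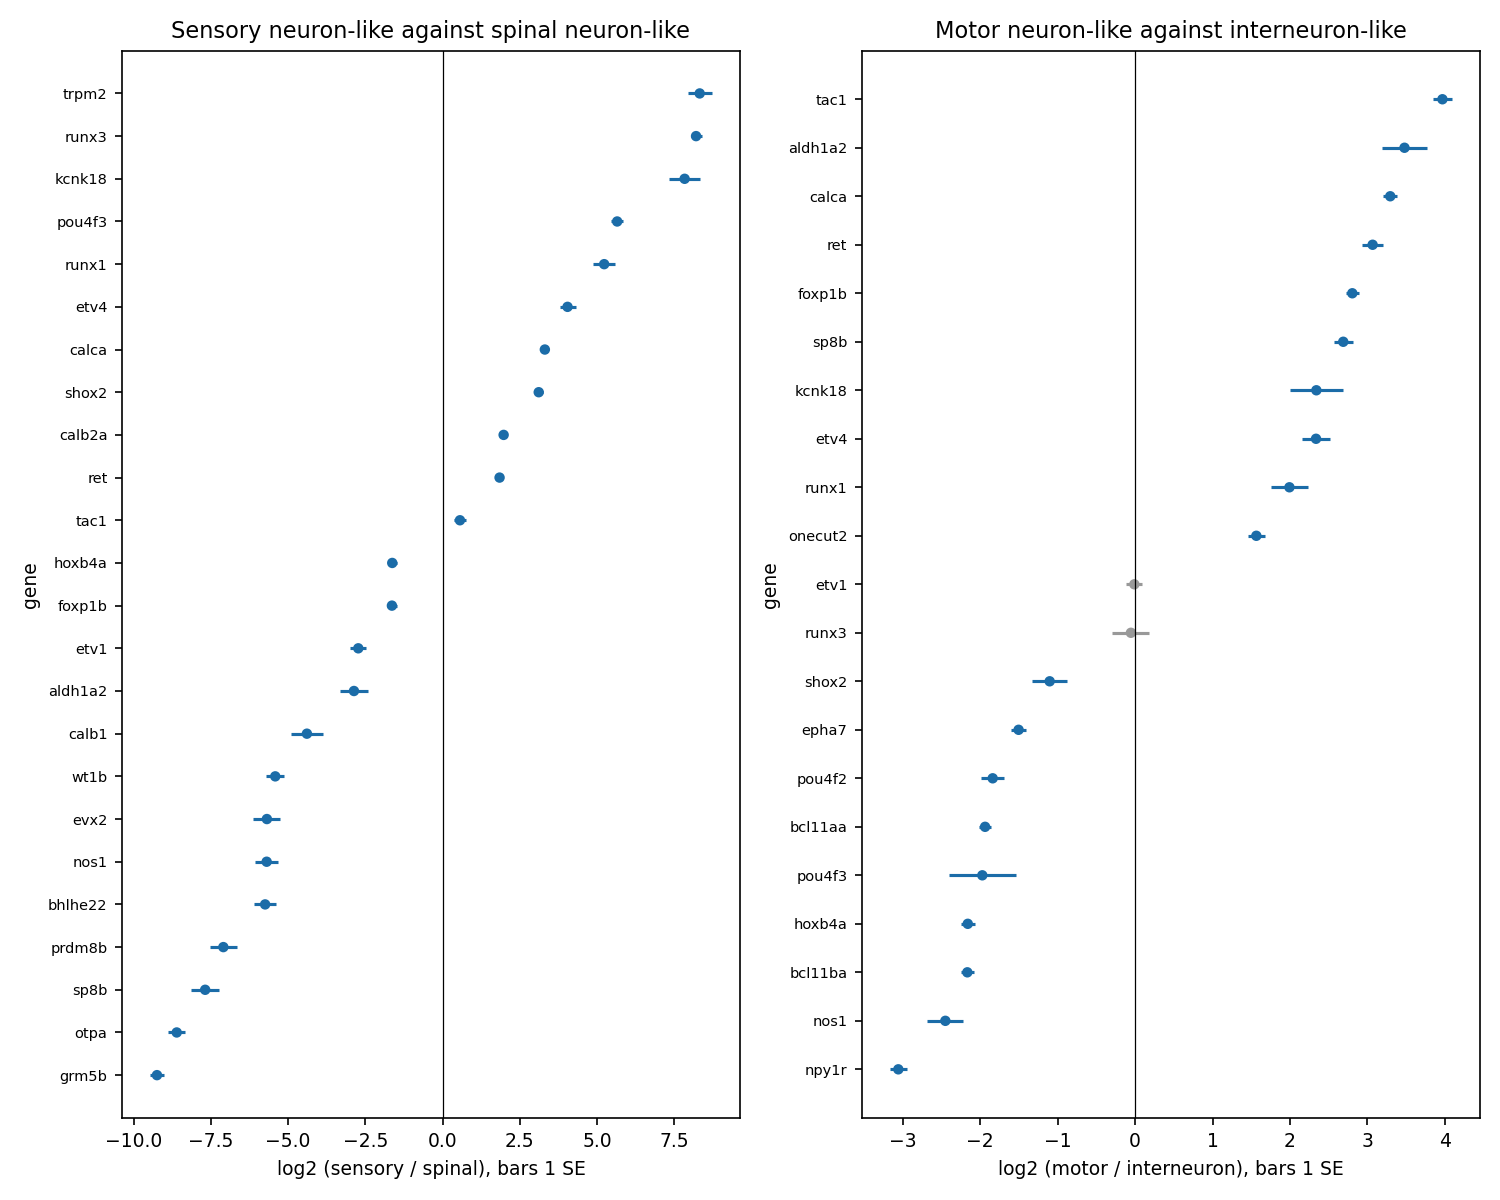
Log2 differences of the list genes named in the text for sensory neuron-like against cord neurons (left) and for motor neuron-like against excitatory interneuron-like cells (right), with 1 SE from the fit over 4 embryos. Blue points passed an adjusted p of 0.05 and grey points did not, from grm5b at -9.25 to trpm2 at 8.32 in the left panel.

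Co-detection was used to ask whether receptors and factors that mark separate sensory neuron types in amniotes lie in the same or in different skate sensory neurons. In 5472 sensory neuron-like cells thinned to 100 counts each, ntrk2a was detected in 63.2 ± 1.08% (SD, n = 4 embryos), runx3 in 40.6 ± 4.14%, ret in 20.6 ± 3.10% and runx1 in 12.5 ± 5.64%. In excitatory interneuron-like cells thinned the same way runx3 was seen in 0.353% and runx1 in 0.249%, against 8.66% for ret and 47.2% for ntrk2a. ntrk2a and ret shared cells more often than independence gives, with a log2 of observed over expected of 0.43 ± 0.13. The pairs ntrk2a with runx3, ret with runx3 and ret with runx1 shared cells less often, at -0.87 ± 0.11, -1.17 ± 0.18 and -1.03 ± 0.34. Without thinning the same 3 values were smaller, at -0.285, -0.44 and -0.17, and that of ntrk2a with ret was 0.27. Each of these 4 pairs had the same sign in 4 of 4 embryos, and the exact two-sided sign-flip permutation test gave p = 0.13, the smallest that 4 embryos allow. ntrk2a with runx1 (-0.12 ± 0.28) and runx1 with runx3 (0.09 ± 0.27) had p = 0.5 in the same exact test. No pair of the 6 could therefore reach 0.05, adjusted or not. The signs of ntrk2a with runx1 and runx1 with runx3 were opposite in embryos a and b (later stage) and c and d (earlier stage). ntrk2a with runx1 stood at 0.07 and 0.16 in a and b, and at -0.39 and -0.32 in c and d. runx1 with runx3 stood at -0.11 and -0.16 in a and b, and at 0.35 and 0.29 in c and d. Within N7 alone the latter split was not kept, with 0.03 in b and -0.007 in d. Whether co-detection differed between the stages was not tested.

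The separation of ret from runx3 lay mostly between the 2 sensory clusters. In N22 ntrk2a was detected in 95.3 ± 2.92% of cells, ret in 52.7 ± 7.54% and runx3 in 5.32 ± 2.60%, whereas in N7 runx3 was detected in 54.7 ± 3.68% and ret in 8.40 ± 2.66%. Within N7 alone ret with runx3 stood at -0.27 and within N22 alone at -0.21, each below 0 in 3 of 4 embryos. ret with runx1 stood at -0.39 ± 0.61 within N7, below 0 in 2 of 4, and at -0.60 ± 0.43 within N22, below 0 in 3 of 4. Within N7 ntrk2a with ret stood at 0.31, above 0 in 3 of 4, and ntrk2a with runx3 at -0.60, below 0 in 4 of 4. In N22 the high share of ntrk2a leaves its pairs almost no room to rise above 0, and its pair with ret little room to fall. Its pair with runx3 had room to fall and stood at -0.0186, with 82 cells against 84.1 expected, above 0 in 2 of 4. ntrk2a helped to name these clusters but did not help to form them.

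**Figure D2:**
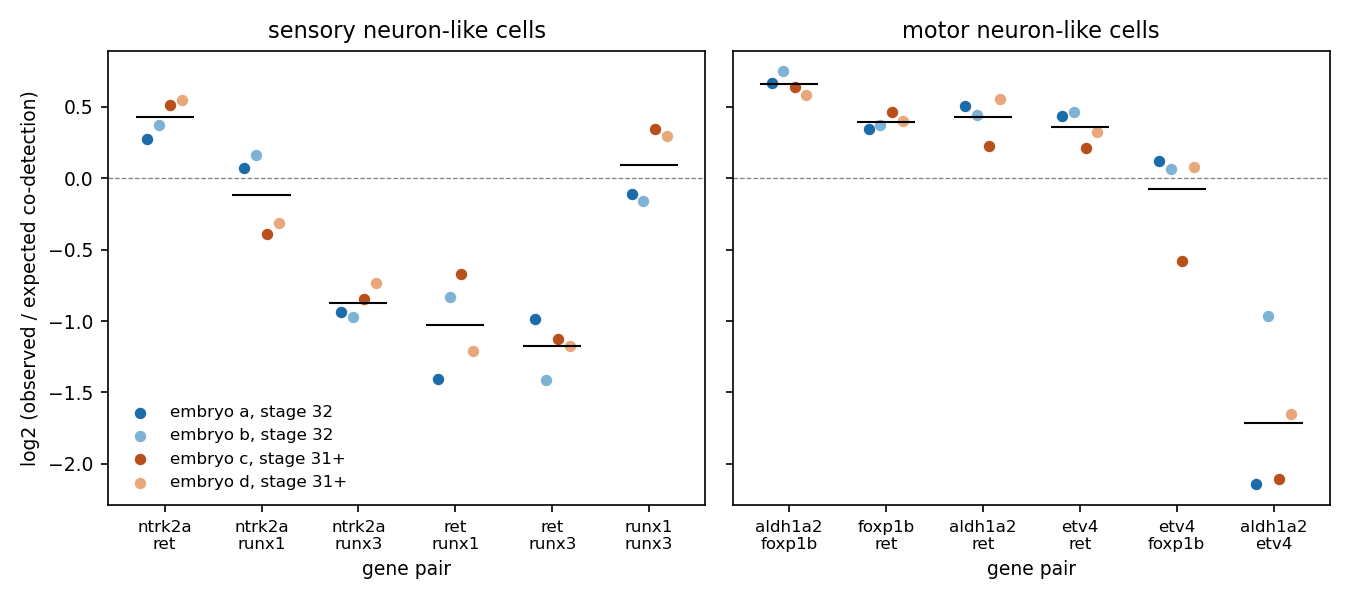
Log2 of the observed over the expected number of cells with both genes, per embryo (points) with the mean (lines), for 6 pairs in sensory neuron-like cells and 6 pairs in motor neuron-like cells, all thinned to 100 counts. Values above 0 mean that 2 genes shared cells more often than independence gives, and in sensory neuron-like cells the lowest mean is -1.17, for ret with runx3.

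The stage comparison asked what differed between stage 32 and stage 31+, with 2 embryos in each. In excitatory interneuron-like cells, leaving N0 aside, gfap and egr3 rose at stage 32. Both genes took part in forming the clusters. RNA of neighbouring cells as a source was weighed for N0 alone and not for the clusters of this class. gfap, an intermediate filament gene of radial glia and astrocytes, stood at 121.8 ± 8.62 per 10000 at stage 32 (SD, n = 2) and at 59.5 ± 7.31 at stage 31+ (n = 2), a log2 difference of 1.004 (SE 0.11, adjusted p = 0.0352). egr3, an immediate early transcription factor that answers neural activity, stood at 1.26 ± 0.189 and 0.177 ± 0.0343, a log2 difference of 2.80 (SE 0.33, adjusted p = 0.0352). gfap was higher at stage 32 in each of the 6 clusters, and also in clusters outside the class such as N6 (354 against 199), N21 (326 against 193), N9 (2962 against 2514) and N12 (2778 against 2337). It was lower in N17 (22.8 against 59.6), N7 (12.4 against 24.5), N22 (8.04 against 17.4), N27 (23.5 against 39.3), N14 (26.5 against 34.0) and N4 (26.5 against 30.3). Among the 6 clusters of the class egr3 was high mainly in N1, at 5.46 ± 1.03 against 0.325 ± 0.222. N1 held the most cells of the class at both stages. These were the 2 of 293 genes past the threshold by edgeR, with 60 at an unadjusted p under 0.05 and 36 past it by DESeq2, which gave gfap and set no adjusted p for egr3. Of 47 list genes 0 passed, and 6 passed adjusted over the list alone. calb2a (0.999), bcl11ba (-0.35) and ebf3a (-0.29) came next without passing, each at an adjusted p of 0.106, and hoxb4a had a log2 of -0.30. The count was 0 with library totals without TMM, on slide 1 alone and at a clustering resolution of 1.0, and it was 19 without embryo a, 11 without b, 7 without c and 10 without d, each time with both genes among them.

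Cluster N0 was compared by number, because drgx, a marker of the sensory class, stood among its leading genes. egr3 rose there from 0.445 ± 0.224 per 10000 at stage 31+ to 15.5 ± 1.14 at stage 32, a 33.8-fold difference (log2 5.08, SE 0.41, adjusted p = 0.00183), and gfap rose from 21.5 ± 3.11 to 98.8 ± 10.9, a 4.51-fold difference (log2 2.17, SE 0.17). bhlhe22 and sox21b rose by 1.81 and 2.50 on the log2 scale and LOC129707396 by 2.92. gfap, sox21b and LOC129707396 are leading genes of the unnamed clusters N12 and N15. Of these only N12 also held the progenitor marker irx3a among its leading genes. The LIM homeobox gene lhx9 fell by 1.25 on the log2 scale and LOC129710853 fell by 0.71. These 7 of 251 genes passed by edgeR, against 24 by DESeq2, and 0 passed without embryo a. Of the 43 list genes 2 passed, and 5 passed adjusted over the list alone. egr3 took part in forming this cluster and is 1 of its leading genes. When clusters were computed without egr3 and gfap, the cluster that took 98.6% of the N0 cells still had egr3 at 14.8 ± 1.06 against 0.429 ± 0.239 and gfap at 128 ± 20.2 against 41.8 ± 2.67, both at an adjusted p of 0.00233.

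**Figure D3:**
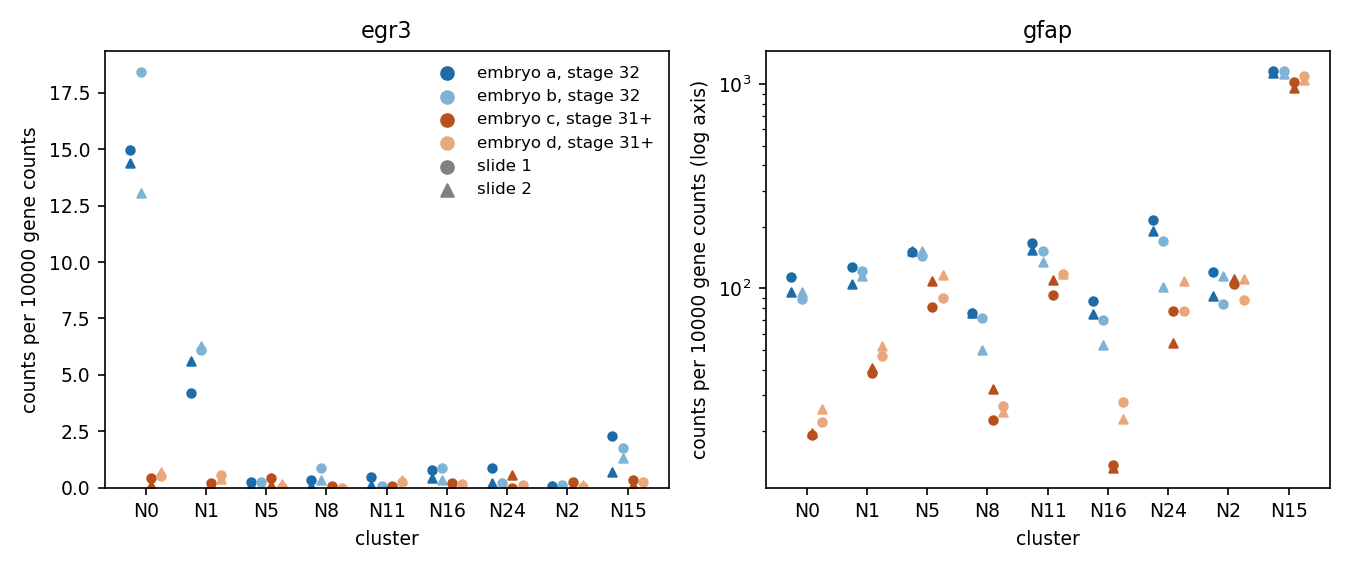
Level of egr3 (linear axis) and gfap (log axis) per 10000 gene counts in each section, for excitatory interneuron-like clusters and comparison clusters, with circles for slide 1 and triangles for slide 2. Among the clusters shown, egr3 stands apart at stage 32 in N0 and N1, with means over embryos of 15.5 and 5.46 per 10000.

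In the sensory neuron-like cluster N7 no gene passed by edgeR, 0 of 234, with 44 at an unadjusted p under 0.05 and 20 past the threshold by DESeq2. The smallest p belonged to runx1, at 8.79 ± 0.00619 per 10000 at stage 32 and 24.8 ± 0.146 at stage 31+ (SD, n = 2 each), a log2 difference of -1.41 (SE 0.19, adjusted p = 0.0721). calb2a, the gene of the calcium buffer calretinin, stood at 288 ± 12.05 against 125 ± 30.5 (log2 1.29, SE 0.18), and gfral at 28.2 ± 4.47 against 63.1 ± 1.03 (log2 -1.08, SE 0.17). LOC129705667, LOC129702179 and isl1a, with log2 differences of 1.20, 2.97 and -0.44, had the same adjusted p. runx3 (-0.17), ret (-0.25), etv4 (-0.38) and ntrk2a (0.02) lay closer to 0. Of 37 list genes 0 passed, and 3 passed adjusted over the list alone. The count was 18 without embryo d, 13 without c and 1 without a.

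In the second sensory cluster, N22, 0 of 220 genes passed by edgeR, with 35 at an unadjusted p under 0.05 and 8 by DESeq2, and 0 of 36 list genes passed adjusted over the list alone. LOC129705667 (log2 1.28), calb2a (1.63), LOC129697058 (1.29), LOC129710599 (0.75) and lgi1b (1.67) had the smallest p, and runx3 stood at -0.99. Whether the stage difference of any gene differed between N7 and N22 was not tested.

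In motor neuron-like cells 0 of 273 genes passed by edgeR, with 44 at an unadjusted p under 0.05 and 18 by DESeq2. bhlhe22 had the smallest p, at 23.2 ± 0.168 against 42.6 ± 2.79 (log2 -0.83, SE 0.15, adjusted p = 0.117, n = 2 per stage). ebf3a and otpa both stood at -0.80 and LOC129708163 at -0.66. etv4, which in mice is set by signals from the limb in motor pools, stood at 25.5 ± 0.901 against 13.6 ± 3.26 (log2 0.95, SE 0.21, adjusted p = 0.138). The preselected genes aldh1a2 (0.30), etv1 (0.39), ret (0.16), chata (0.04), mnx1 (-0.06), foxp1b (-0.10), isl1a (-0.30) and hoxb4a (-0.30) did not pass. With 1 embryo left out aldh1a2 ranged from -0.19 to 1.18. Of 47 list genes 0 passed, and 3 passed adjusted over the list alone. The count was 1 without embryo d.

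Over whole sections 0 of 300 genes passed by edgeR, with 52 at an unadjusted p under 0.05, 43 of them higher at stage 32, and 21 past the threshold by DESeq2. LOC129715185 stood at 1034 ± 36.9 per 10000 at stage 32 and 657 ± 21.4 at stage 31+ (log2 1.01, SE 0.20, adjusted p = 0.0532, n = 2 per stage). LOC129706748 (1.24), LOC129709864 (1.35, opposite in direction on the 2 slides), egr3 (1.34) and LOC129705887 (1.20) came next. runx3 stood at 0.90 (adjusted p = 0.171) and runx1 at -0.49, while aldh1a2 (-0.35), isl1a (-0.34), ntrk2a (-0.16), etv4 (-0.14), hoxb4a (-0.14), ret (-0.12), chata (-0.09), mnx1 (-0.07), foxp1b (-0.05) and etv1 (0.00) lay near or below 0. LOC129709864 and runx3 are leading genes of T21, which made up 2.71 ± 1.06% of kept cells at stage 32 and 0.807 ± 0.334% at stage 31+. LOC129715185 is a leading gene of T10 among others, at 6.42 ± 3.75% and 2.07 ± 0.0311%. Neither share passed, and whole-section values cannot tell expression from the mix of cells. With library totals without TMM the median gene shifted by -0.36 on the log2 scale, and with TMM by -0.01, so these values are relative to the bulk of the panel. Of 48 list genes 0 passed, alone or with the panel. The count was 23 without embryo d, 7 without c and 3 without a.

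As sets, the spinal interneuron identity genes lay lower at stage 32 by camera with its preset correlation in whole sections (adjusted p = 0.0338, 4 of 20 genes higher), N7 (0.0153, 1 of 11), motor neuron-like cells (0.00409, 4 of 20) and interneuron-like cells (0.0122, 6 of 20), with median log2 differences of -0.31, -0.33, -0.27 and -0.25. The same 4 tests gave adjusted p = 0.921, 0.398, 0.390 and 0.517 with an estimated correlation, so none of them held. etv1, etv4, ret and runx1 stand on both the sensory and the motor neuron subtype list. The motor neuron subtype genes lay lower in N7 (0.0180, 0 of 6 higher, median -0.39), with adjusted p = 0.398 with an estimated correlation. In motor neuron-like cells the same list went the other way without passing (camera adjusted p = 0.0600, 5 of 7 higher, median 0.39), and it gave 0.333 in interneuron-like cells and 0.777 in whole sections. By fry the interneuron identity genes moved lower together in N7 (adjusted p = 0.0185) and motor neuron-like cells (0.0492), and not in interneuron-like cells (0.0855) or whole sections (0.680). Both fry calls were lost whichever embryo was left out, with adjusted p of 0.0660 to 0.551 in N7 and 0.168 to 0.249 in motor neuron-like cells. For the other lists camera gave adjusted p from 0.118 to 0.896 for sensory subtype genes, 0.0981 to 0.942 for neuropeptides, 0.615 to 0.896 for channels and 0.118 to 0.777 for guidance genes. Median and test differed in sign for neuropeptides in N7 (median 0.36) and guidance genes in motor neuron-like cells (median -0.03), and for sensory subtype genes in whole sections camera gave lower and fry higher. In N7 the sensory subtype, interneuron identity and neuropeptide genes changed by the fry test for change in either direction, each at an adjusted p of 0.000940, as did the motor neuron subtype genes (0.00811) and, in interneuron-like cells, the sensory subtype (0.0367) and interneuron identity genes (0.0357). Each of these 6 calls was lost with at least 2 of the 4 embryos left out in turn, and 3 of them with all 4. Of the 5 camera calls, 2 were kept without embryo a, 1 without b, 1 without c and 3 without d. The call kept each time was that of the interneuron identity genes in motor neuron-like cells.

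Class sizes were compared as shares of kept cells. The N7 share was 0.304 ± 0.0996% at stage 32 and 0.439 ± 0.0481% at stage 31+ (SD, n = 2 each), that of motor neuron-like cells 0.368 ± 0.0972% and 0.564 ± 0.165%, and that of interneuron-like cells without N0 1.93 ± 0.281% and 2.35 ± 0.587%. By edgeR 0 of 51 classes and clusters passed, with 10 at an unadjusted p under 0.05 and the smallest adjusted p at 0.0626. The non-neural clusters T21 (log2 1.75) and T10 (log2 1.63) had the smallest p. The count was 3 without embryo a, 1 without b, 2 without c and 6 without d. Clusters left out of the classes by their markers had shares at stages 32 and 31+ of 0.718 and 0.828% in N0, 0.135 and 0.158% in N22, 0.204 and 0.218% in N17, 0.313 and 0.387% in N15, 0.322 and 0.260% in N14, and 0.0615 and 0.0752% in N27.

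The last comparison measured how far the 2 sections of the same embryo differed between slides. runx3 was lower on slide 2, at 2.91 ± 0.569 per 10000 (SD, n = 4 sections) against 11.3 ± 4.56 on slide 1, a log2 difference of -1.54 (SE 0.29, adjusted p = 0.0163). Its highest level was in the non-neural cluster T21, at 362 per 10000 against 100.3 in N7, and T21 was nearly absent on slide 2. c1ql2, which encodes a secreted synaptic protein and was among the leading genes of motor cluster N2 and of the non-neural cluster T28, was 4.10-fold lower, tekt3 3.83-fold lower and LOC129697058 8.50-fold lower. The last 2 lead the non-neural cluster T19, which went from 3.94% of kept cells on slide 1 to 0.572% on slide 2. LOC129708132 was 2.08-fold higher on slide 2, and the muscle genes xirp2a and alpk2 were higher by 0.72 each on the log2 scale. Among the preselected genes isl1a (-0.40), etv1 (0.39) and runx1 (0.24) passed as well, and runx1 turned to -0.10 with library totals without TMM. By edgeR with embryo as a block, 104 of 300 genes passed, 55 higher and 49 lower on slide 2, with 151 at an unadjusted p under 0.05 and 151 past the threshold by DESeq2. Library totals without TMM gave 191 genes, 13 of them higher, and moved the median gene by -0.34. The count was 28 without embryo a, 50 without d and 68 without b. Within neuron classes fewer genes passed, 5 of 234 in sensory neuron-like cells, 5 of 262 in motor neuron-like cells and 24 of 293 in interneuron-like cells. Over all clusters taken as neural, N0 to N30 together, 48 of 299 passed by edgeR, with 125 at an unadjusted p under 0.05. Whether the slide difference differed between stages was tested directly, and 0 of 300 genes passed by edgeR, with 46 at an unadjusted p under 0.05.

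**Figure D4:**
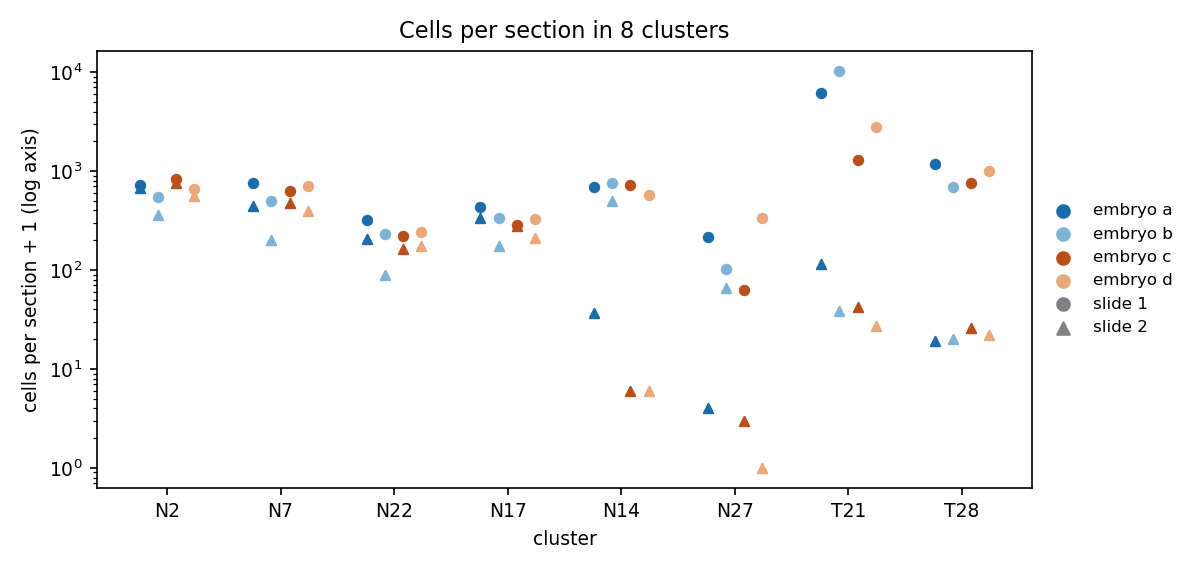
Number of cells plus 1 per section (log axis) in clusters N2, N7, N22, N17, N14, N27, T21 and T28, with circles for slide 1, triangles for slide 2 and 1 colour per embryo. T21 made up 3.42% of kept cells on slide 1 and 0.0380% on slide 2, and N14 and N27 together went from 2596 to 51 cells in embryos a, c and d.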

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

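Of the tests in this part, the share of the slide difference that cluster sizes return and the test of RNA from the cluster with the highest egr3 level were written before their result was seen, and all others were chosen after it. One signal lay in data outside the comparisons: the highest of the 180 unassigned codewords, which stand for no probe, collected 3562 counts over all sections, above the highest negative control codeword at 3206. It was the only 1 of 180 above that level, the median unassigned codeword held 59.0 counts, and the median gene held 131780.0. In 30 tests for a section far from the others of its group, on 15 measures, with the sections of an embryo taken singly, 0 were past Dixon's limit.

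The genes that differed between slides, such as runx3, c1ql2 and xirp2a, were weighed first. Within the 3 neuron classes the median shift in the direction of the whole section was at most 0.0865 on the log2 scale, against 0.446 in whole sections. This argued against a staining or imaging difference that moves the same genes in all cells. Each sum was rescaled, so a difference in yield common to all genes was not weighed. Median counts per cell were higher on slide 2 in each embryo, from 78.0 to 85.0 in a, 89.0 to 96.0 in b, 103.0 to 113.0 in c and 98.0 to 129.0 in d. Nor do these classes cover losses confined to non-neural clusters such as T21, where runx3 stood highest. Cluster sizes on each slide with shared profiles returned 0.309 of a median shift of 0.405, taken here as the mean of the log2 ratios of the embryos, a share of 0.765, so different tissue in the sections could account for most of it. Cells were assigned to clusters from the same counts, so this test was not independent of expression. Exchanging the slides within embryos allows 8 splits, too few for a share under 0.05, and the real one alone (1 of 8) gave as many genes, 104 and 0 in the highest other.

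The stage 32 rise of egr3 and gfap in N0 was weighed against RNA of neighbouring cells. Clusters N12 and N15 both have gfap among their leading genes. If the gfap rise came from them, a fraction of 3.93% of their profile was needed. Their other leading genes rose by a median of 0.262 of the amount this predicts, with 7 of 13 rising and ratios from -3.60 to 0.880. sox21b (0.880) and LOC129707396 (0.679), which also passed in N0, were among the highest. Spill-over from N12 and N15 cells could therefore explain a part of the rise, and the source of gfap stayed open. For egr3 the same fraction brought 0.225% of the rise and cluster T20, with the highest egr3 level, brought 0.612%, which argued against both sources. T20 lay outside the clusters taken as neural, but its leading genes held egr2b, a marker of Schwann or satellite glia. A difference in the N0 cells themselves between the stages stays open for egr3 and was not tested further.

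Clusters N14 and N27 almost vanished on slide 2 in embryos a, c and d, from 2596 to 51 cells, and in b went from 860 to 558. In the same 3 embryos N7 went from 2088 to 1316 cells, 11.8% of the log2 fall of N14 and N27, which argued against a general loss of neurons. The log2 fall in embryo b was 11.03% of that in the others, which argued against a staining difference of the slide for N14 and N27. The non-neural clusters T21 and T28 nearly vanished on slide 2 in all 4 embryos, in b from 10362 to 38 and from 697 to 19 cells, and for these a cause common to the slide stays open. A structure with N14 and N27 cells that the second section of a, c and d missed could explain both values, and this was not tested, since positions were not used here.

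For the stage tests the 4 embryos allow 3 splits, too few for a share under 0.05. In interneuron-like cells 1 of 3 splits, the real one, gave as many genes (2, and 0 in the highest other), and in N0 likewise 1 of 3 (7, and 0). In whole sections, N7, motor neuron-like cells and N22 all 3 of 3 gave as many, since the real split and the highest other both gave 0. For the contrasts of classes, exchanging the classes within embryos allows 8 splits, again too few for a share under 0.05. The real one alone gave as many genes, 1 of 8 for sensory neuron-like against cord neurons (40, and 0 in the highest other) and 1 of 8 for motor against interneuron-like cells (29, and 0).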

How the results depend on the processing

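Among the alternatives, clusters N7 and N22 alone, the tests of N0 and N22, the classes without N0 and N22 and the clusters without egr3 and gfap were chosen after results were seen, and the others before. Of the values of main results under an alternative 116 kept their side or size, 63 moved and 1 reversed. Of the values of named genes and lists 1942 kept their side of the threshold, 108 of them with a change of sign while past it in neither fit, 77 newly passed, 80 no longer passed and 5 reversed. Where a value below differs, the cause was not tested. A lone embryo left in a stage is assumed to vary like the others.

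In the class contrasts the sensory count stayed between 37 and 41 and the motor count between 26 and 31, with 39 and 28 without the replicate block. With N0 and N22 left out of the classes the counts were 40 and 27, but ret reversed to -0.94 in the sensory contrast, because N22 holds most of the ret of the class. The block mattered for the slide count, which was 19 without it (18 shared) and 191 with library totals without TMM, and 28 to 80 with 1 embryo left out. Without TMM 4 genes turned from higher to lower on slide 2, aldh1a2 (-0.24), foxp1b (-0.18), ret (-0.25) and runx1 (-0.10). Leaving out TMM moves the median gene by -0.34, so small positive values turn by construction.

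Stage counts moved with the tool and with the embryos. DESeq2 gave 21 genes in whole sections, 20 in N7, 18 in motor and 36 in interneuron-like cells, 24 in N0 and 8 in N22. The random block of embryo over 8 sections gave 2, 19, 5, 11, 12 and 2 in the same order. With 1 embryo left out the counts were 0 to 23, 0 to 18, 0 to 1, 7 to 19 and 0 to 10 for whole sections, N7, motor, interneuron-like cells and N0. Cells of 40 or more counts gave 6 in whole sections, and slide 1 only gave 1 in N7. In interneuron-like cells the count was 0 without TMM, 0 on slide 1 only, 4 on slide 2 only, 0 at a resolution of 1.0 and 1 at 4.0. runx1 in N7 ranged from -1.68 to -0.82 on the log2 scale.

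For class shares the count was 6 at a resolution of 1.0 and 1 to 6 with 1 embryo left out. For gene lists 0 of 5 calls were left with the estimated correlation. With 1 embryo left out there were 1 to 4 calls, of which 1 to 3 were among the 5, since leaving out c and d each added 1.

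Co-detection kept its sign for 4 pairs except in 1 case, and its size depended on depth. Without thinning the log2 values were 0.27 for ntrk2a with ret, -0.285 for ntrk2a with runx3, -0.17 for ret with runx1 and -0.44 for ret with runx3. With thinning to 50 counts ntrk2a with runx3 stood at -1.23 and ret with runx3 at -1.62. At 2 or more counts the pairs stood at 0.59 for ntrk2a with ret, -0.55 for ntrk2a with runx1, -2.02 for ntrk2a with runx3, -1.77 for ret with runx1, -2.82 for ret with runx3 and 0.49 for runx1 with runx3. Within N7 alone ntrk2a with runx3 was -0.60, ret with runx1 -0.39 and ret with runx3 -0.27. Within N22 alone ntrk2a with ret reversed to -0.0297, ntrk2a with runx3 was -0.0186, ret with runx1 -0.60 and ret with runx3 -0.21. ntrk2a was in 95.3% of N22 cells, so its values there can hardly rise above 0. With ret, in 52.7% of these cells, it can hardly fall either, and that sign says nothing. With runx3, in 5.32%, it could have fallen.

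Depth limits the rarest genes. At 100 counts per cell runx1 was seen in 12.5% of sensory neuron-like cells, against 37.3% without thinning, and ret in 20.6 against 37.2%.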

Other observations

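In motor neuron-like cells, pairs of motor neuron genes were examined after the other results were seen, with predictions for 2 of the 36 pairs written after their values. aldh1a2 and foxp1b, which mark limb-level motor neurons in tetrapods, shared cells more often than independence gives in 4 of 4 embryos, with 523 cells against 333 expected and a log2 value of 0.66 ± 0.07 (SD, n = 4 embryos). aldh1a2 and etv4 shared cells less often in 4 of 4 embryos, with 24 cells against 78.3 expected and a log2 value of -1.72 ± 0.55. foxp1b with ret (0.40), aldh1a2 with ret (0.43) and etv4 with ret (0.36) lay above 0 in 4 of 4 embryos, and aldh1a2 with calca (-0.40) below 0. These cells had tac1 in 84.7%, foxp1b in 45.1%, calca in 43.6%, ret in 40.5%, aldh1a2 in 15.2%, etv4 in 10.8% and etv1 in 7.44% when thinned to 100 counts. The exact sign-flip permutation test over 4 embryos cannot go below 0.13, so none of the 36 pairs passed. etv4 with foxp1b stood at -0.08. The pairs were picked for their values, so 0.66 and -1.72 decide nothing about groups of motor neurons.

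Outside N0 and N1, egr3 in N15 was at a mean of 1.58 per 10000 at stage 32 and 0.174 at stage 31+. In N27 it was at 5.72 ± 3.34 per 10000 at stage 32 and 0.490 ± 0.693 at stage 31+, and in N17, which carried egr2b, runx1 and pou4f3 among its leading genes, at 4.22 ± 2.90 and 1.91 ± 0.339 (SD, n = 2 embryos per stage), with section a2 of stage 32 (1.31) below sections c1 (2.78), d1 (1.94) and d2 (2.38) of stage 31+. N14 was led by six2a, s100z, omd, aldh1a3 and gfral, and N27 by six2a, hmx1 and runx1. In N2, the motor cluster, egr3 was at 0.0747 and 0.124 and gfap at 101.3 and 103.5, close to each other at the 2 stages. In N7 gfap was at 12.4 ± 8.14 at stage 32 and 24.5 ± 6.96 at stage 31+. gfap was higher at stage 32 in N3 (92.8 against 69.7), N15 (1149 against 1032) and N26 (1817 against 1337) as well. These levels by cluster were not tested.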
